A study of Oryza sativa with 6 samples.

How the data were processed

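Roots of rice (Oryza sativa, cultivar Nipponbare) were compared between wild type and serf1, a line carrying a T-DNA insertion. Per the labels, plants grew for 4 weeks in hydroponic boxes on Yoshida medium with a 12 h day at 26 °C and nights at 22 °C, 700 µmol of light per square metre and second, and 75% and 70% relative humidity by day and night. Each genotype has 3 arrays, which the labels describe as separately isolated biological replicates, and 5 µg of RNA went into each labelling. Groups and replicate numbers were taken from the sample titles.

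The deposited values are signal intensities on a linear scale, 1 per probe set and array, from a 1-colour Affymetrix rice array. MAS5 is named in the submitters' processing notes, with its version not given in the sources used here. A trimmed mean over the middle of each array's values, leaving out 2% at each end, came to 100.0 on every array, so the deposited intensity values were already scaled per array. Detection calls were not used here. No 2 arrays shared more than 1.64% of their values, so no array was counted as a duplicate. For arrays, their number limits the precision.

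Of the 57381 probe sets, 123 Affymetrix controls were left out. Values listed at 0 (between 3 and 8 per array) were set to 0.1, the lowest positive value, and log2 was taken without an offset. Probe sets were kept when their mean log2 signal over the 6 arrays reached the median, 4.17, which corresponds to a signal of 18.0 and left 28629. The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), a two-sided moderated test without covariates, and Benjamini-Hochberg adjustment at 0.05. All p-values per probe set come from this model.

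The array carries 64 reporter probe sets. As 1 of them was bright in serf1, the other 63 served as a measure of background, chosen after seeing the data: the 95th percentile of their signal was 19.0 to 34.3 per array. Where all 3 arrays of a genotype lay under it, the ratio is given as a bound, from means of log2 values with each array of the dim genotype raised to at least its own background.

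Names came from GEO's platform annotation, which is old, updated by gene identifier through the RefSeq table of assembly ASM3414082v1. It pairs 22436 probe sets with 1 gene and 95 with several, and does not list 34850. All 17905 genes were matched in the RefSeq table, but only 2440 carry a name that says what they are and the other 15465 have a locus or clone number. Probe sets of several genes were not named. No coordinates are given. A probe set of SERF1 itself was not analysed here, nor were MAP3K6 and ZFP179, because no name in the tables matched.

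The themes of 32 gene lists were fixed before the data were examined, and a circadian clock list was added later. Membership was to be taken from gene descriptions, which the tables lack. It was therefore set from patterns in gene names, written after the tables were opened and before any fold change of a list or its members was looked at. Each gene was represented by its brightest probe set. Lists with at least 5 measured genes (29 of them) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Marker lists covered shoot tissue, seed remnants, meristem, endodermis and root hairs, and 3′ to 5′ signal ratios of control genes were taken as signs of RNA quality.

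Genes named in the text followed a rule set before the data were examined. It takes the study's genes, then in each direction the 12 largest changes past the threshold among genes with an informative name and genotypes that do not overlap. Where fewer than 6 such genes pass in a direction, it takes the 6 with the smallest p. For each list it takes up to 4 members past the threshold, or the 2 with the smallest p. No called probe set has an informative name, so the called probe sets are described outside that rule, after their values were seen, and the plot of their signals gives their identifiers.

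The procedure was tested on simulated data with the means and spreads of the 28629 probe sets, 200 of them changed, in 10 runs with independent noise and 10 in which arrays also shared the first component of the real residuals in permuted order. With independent noise it recovered 23.2% of changes of 1 on the log2 scale, 64.4% of changes of 2, 77.4% of changes of 3 and 91.8% of changes of 5, with 7.7 false calls per run. With the shared component it recovered 21.4%, 68.0%, 84.8% and 94.4%, with a mean of 553 false calls per run, a median of 1 and a highest value of 5514.

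Alternatives covered the filter, an offset of 16 or 64 before log2, quantile normalization, median centring, the variance model, array weights, the replicate number as a block, leaving out each array, and other thresholds. A component covariate, a background floor and leaving out reporter probe sets were added after seeing the data.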

Results

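Gene expression was measured in roots of 4-week-old rice plants of the wild type and of serf1, a T-DNA line named for SALT-RESPONSIVE ERF1, with 3 arrays per genotype. The comparison asks which transcripts differ between the genotypes in plants grown without added salt, as far as the labels describe the medium. Median signal was between 17.9 and 24.5 per array, highest on wild type 3, and between 42.8% and 50.2% of probe sets lay above the reporter background of their array.

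Few probe sets passed the threshold between serf1 and wild-type roots, and those that did changed by large factors. The count does not show that few transcripts differ, as small changes would mostly be missed. In the simulated data, 21.4% to 23.2% of log2 changes of 1 and 64.4% to 68.0% of changes of 2 were recovered. Those data held 200 changed probe sets. The adjustment is stricter where fewer probe sets change, so these shares may be too high for the real data. Of 28629 probe sets, 7 passed an adjusted p of 0.05 in limma, 6 higher and 1 lower in serf1. One of the 6 is a reporter control and not a rice gene, which leaves 5 rice probe sets higher and 1 lower. Wild-type roots had almost no signal for LOC4331398, a gene named only by its locus, while all 3 serf1 arrays were bright. Its probe set with the smallest p measured 10.7 ± 2.20 in wild type and 1680 ± 302 in serf1 (SD, n = 3 arrays each; limma adjusted p = 2.5e-04), at least 65.8-fold higher in serf1 because all 3 wild-type arrays were under the background.

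A second probe set of LOC4331398 measured 10.4 ± 9.59 in wild type and 1757 ± 315 in serf1, at least 68.8-fold higher, with a limma adjusted p of 0.174 that misses the threshold. LOC4340325, also named only by its locus, was 20.4-fold higher in serf1 by 1 probe set (limma adjusted p = 0.016), with 2 of the 3 wild-type arrays under the background. Its other probe set did not pass and gave 48.6 ± 7.60 in wild type and 54.0 ± 7.68 in serf1, so the probe sets of this gene disagree.

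The remaining rice probe sets have no gene in the annotation used. The brightest of them rose from 58.1 ± 30.6 to 3626 ± 206, a 68.9-fold difference (limma adjusted p = 0.00775). Another rose from 66.6 ± 14.1 to 1319 ± 195, or 19.9-fold (limma adjusted p = 0.0025). The dimmest of those that rose was at least 9.80-fold higher in serf1, at 251 ± 45.9 against 1.5 ± 0.755 (limma adjusted p = 0.00675). The probe set that fell went from 110 ± 13.0 in wild type to 9.60 ± 3.36 in serf1, at least 5.08-fold lower (limma adjusted p = 0.031).

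**Figure D1:**
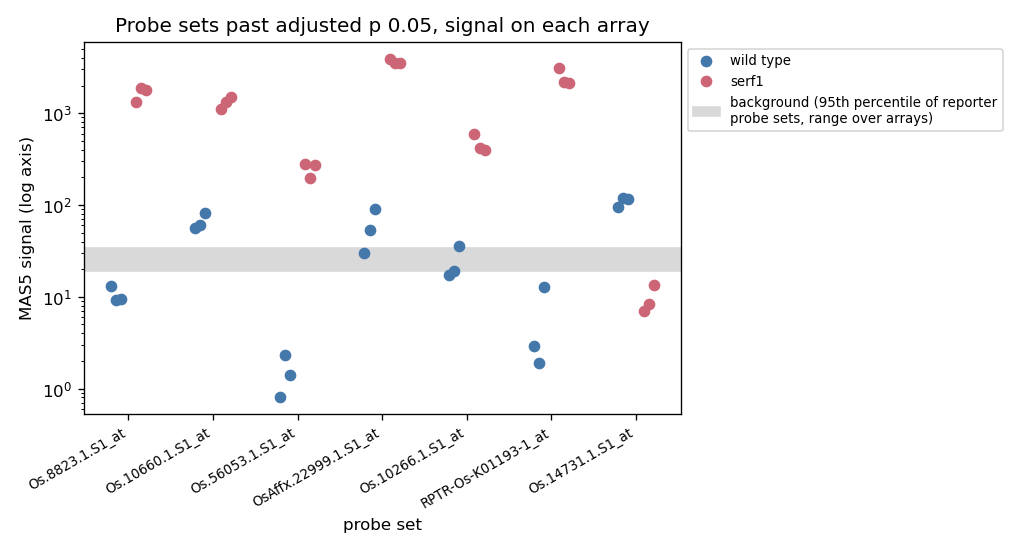
MAS5 signal on a log axis for the 7 probe sets past the threshold, 1 point per array, with wild type in blue, serf1 in red and a grey band for the range of the background over the 6 arrays. The genotypes do not overlap in any of the 7, and the probe set at the right end is the 1 that is lower in serf1.

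SERF1's own probe set was not analysed here, so the labels have no check on the targeted gene. The reporter probe set, the brightest of 64 on any array, was looked at after its values were seen, and the tables used do not tie it to the T-DNA. It measured 2471 ± 544 on the serf1 arrays and 5.90 ± 6.08 on the wild-type arrays, at least 96.4-fold higher in serf1 (limma adjusted p = 0.016).

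Only the first probe set of LOC4331398 passed whichever array was left out. The count of 7 became 3 without wild type 2, 2 without serf1 1, 1 without serf1 2 and 2 without serf1 3. The log2 differences of the 7 kept their direction in these fits, which rest on fewer arrays, and moved by at most 0.82. At an unadjusted p under 0.05 there were 1086 probe sets, where chance alone gives 1431. That number was above chance without wild type 3, at 2212, and without serf1 1, at 2252, and between 612 and 628 without each of the other arrays. Without wild type 3 or serf1 1, the remaining arrays of that genotype share a side of the first principal component, described below. The higher counts in those fits can therefore not be read as a difference between genotypes. Genotypes did not overlap in 10.2% of probe sets, where chance gives 10%.

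DREB2A and MAPK5, genes followed in the study of this line, did not pass. DREB2A, a transcription factor of dehydration and heat responses, measured 44.1 ± 9.77 in wild type and 34.6 ± 2.96 in serf1 (log2 difference -0.33, SE 0.23, limma adjusted p = 0.959). Its signal was above the background on every array, but only just on wild type 3, at 34.7 against 34.3. MAPK5, a stress-activated protein kinase, measured 364 ± 94.8 and 311 ± 74.0 (log2 difference -0.22, SE 0.26, limma adjusted p = 0.959).

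No gene with an informative name passed in either direction. The 6 with the smallest p and higher values in serf1 were AOC, HOX12, GBSS1, PIK6-NP, SAM2 and PIN2. AOC, allene oxide cyclase of jasmonate synthesis, measured 500 ± 51.1 in wild type and 1080 ± 224 in serf1, 2.14-fold (limma adjusted p = 0.775). HOX12, a homeobox gene, gave 1.75-fold, and PIN2, an auxin efflux carrier, gave 1.46-fold. GBSS1, a starch synthase, had wild-type values under the background and was at least 1.09-fold higher in serf1 in value, without passing. The 6 on the lower side were RTUB-2, AGL10, CIPK17, HAK3, AMT3-1 and NSHB1. RTUB-2, a tubulin, measured 236 ± 17.1 and 138 ± 6.42, 1.71-fold lower in serf1 (limma adjusted p = 0.959). HAK3, a potassium transporter, gave 1.58-fold lower and the haemoglobin gene NSHB1 1.29-fold lower. Other probe sets disagreed for RTUB-2 (log2 differences of 0.21 and 0.11), for AMT3-1 (0.36), whose lower probe set had all 3 serf1 arrays under the background, and for SAM2, at 2006 in wild type and 1968 in serf1.

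Across the gene lists, 0 of 736 measured genes passed limma's adjusted p over all probe sets. Adjusted over the list alone, 1 gene passed, AOC among the 35 measured genes of jasmonate synthesis and signalling. It was higher in 3 of 3 serf1 arrays (limma adjusted p = 0.0199 over the list alone). That adjustment does not correct for the number of lists, so 1 pass among them is weak evidence. The other 34 of that list did not pass, and AOS3 measured lower in serf1, with 2 of its 3 serf1 arrays under the background.

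Histone and cell cycle genes, markers of the meristem, had 86 measured members, of which 67 had higher and 19 lower means in serf1, with a median log2 difference of 0.22 and none past the threshold. The kinesins KIN14N and KIN14L had log2 differences of 0.67 and 0.51. Camera at the preset correlation put the list higher in serf1 (adjusted p = 6.6e-04), and the adjusted p = 0.925 with an estimated correlation. Pathogenesis-related proteins had lower means for 19 of 22 members, a median of -0.38 and none past the threshold (camera adjusted p = 0.0159, and adjusted p = 0.925 with an estimated correlation). Its examples were chitinase at -0.40 and XIP-I at -0.73. Auxin response genes had higher means for 35 of 54 members, a median of 0.18 and none past the threshold (camera adjusted p = 0.0425, and adjusted p = 0.925 with an estimated correlation). PIN2 of that list had a log2 difference of 0.55, and IAA8 was at least 1.16-fold higher in serf1 in value, with all 3 wild-type arrays under the background. Each of the 3 calls was lost without wild type 2 (adjusted p = 0.108 for the histone and pathogenesis-related lists and 0.139 for the auxin list) and without serf1 3 (adjusted p = 0.127 for all 3). Without wild type 1 or serf1 2 the pathogenesis-related list (adjusted p = 0.567 and 0.364) and the auxin list (0.279 and 0.134) were lost too, and the auxin list also after quantile normalization (adjusted p = 0.0859), with the stricter filter (0.126) and with the mean of all probe sets of a gene (0.0702).

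None of the 29 lists passed fry in one direction (smallest adjusted p = 0.973) or in mixed directions (smallest adjusted p = 0.859). In simulated arrays that shared the main component of the residuals and held no change, camera at the preset correlation called a median of 8.5 and up to 11 of the 29 lists, and none with an estimated correlation.

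Among other lists tied to salt and water, ABA signalling and synthesis had 65 measured genes, sodium and potassium transport 27, aquaporins 21, the MAPK cascade 16, LEA proteins and dehydrins 9, and AP2/ERF and NAC transcription factors 7 each. None of these genes passed, and the camera adjusted p of these lists lay at 0.387 for the MAPK cascade, 0.482 for LEA proteins, 0.585 for NAC genes, 0.911 for ion transport and 0.916 for ABA genes, aquaporins and AP2/ERF genes. The salt-induced gene salT had a log2 difference of -0.81 with an SE of 0.80 by its brightest probe set. That probe set measured 4316 to 5104 on wild type 1, wild type 2 and serf1 1 and 711 to 1458 on the other arrays. Another probe set named salT, not among the 7 called, had a log2 difference of -1.33 in the fit with the component covariate. Of the tissue markers, photosynthesis genes had lower means for 6 of 7 members with a mean log2 difference of -0.54 (camera adjusted p = 0.0747), and the 22 endodermis genes gave an adjusted p of 0.916. Seed storage and root hair markers had 3 measured genes each and were not tested.

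The largest difference between arrays did not follow genotype. The first principal component held 60.01% of the variance and set wild type 1, wild type 2 and serf1 1 apart from wild type 3, serf1 2 and serf1 3. The second component, with 14.6% of the variance, separated the genotypes completely, with wild type at -44.7 to -16.4 and serf1 at 21.9 to 29.2. Across probe sets, wild type 1 correlated with serf1 1 at r = 0.971 and with wild type 3 at r = 0.906, and wild type 3 with serf1 3 at r = 0.962, where probe sets are not independent replicates. The means of the histone list moved with this component, from -0.28 to -0.21 on wild type 1, wild type 2 and serf1 1 and from 0.20 to 0.29 on the others, as did those of the pathogenesis-related list, from 0.37 to 0.57 and from -0.55 to -0.35, and of the auxin list, from -0.20 to -0.04 and from 0.10 to 0.14.

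**Figure D2:**
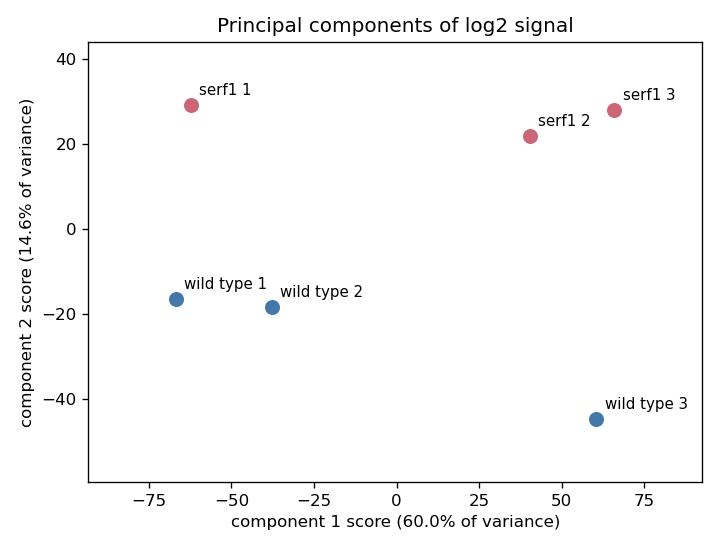
Scores of the 6 arrays on the first component (60.01% of variance, horizontal axis) and the second (14.6%, vertical axis) of log2 signal, 1 labelled point per array, wild type in blue and serf1 in red. The first component parts wild type 1, wild type 2 and serf1 1, at -66.8 to -37.8, from the other arrays, at 40.4 to 65.9, and the second parts wild type, at -44.7 to -16.4, from serf1, at 21.9 to 29.2.

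The 3′ to 5′ ratios of the 4 control genes overlapped between genotypes, and that of actin parted the arrays along the first component. The ratio of actin was 4.46 ± 0.273 in wild type and 4.79 ± 0.384 in serf1 (SD, n = 3), and that of GAPDH 2.46 ± 0.323 and 2.48 ± 0.134. That of cyclophilin was 2.70 ± 0.541 and 2.87 ± 0.315, and that of ubiquitin 0.734 ± 0.018 and 0.751 ± 0.03. The 18S and 28S ribosomal RNA controls were higher on all serf1 arrays than on all wild-type arrays, while the 25S and 5.8S controls overlapped.

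**Figure D3:**
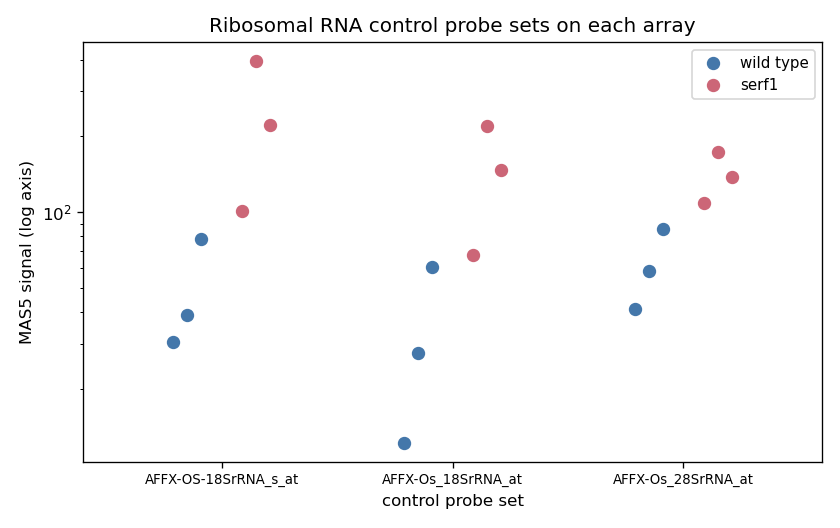
MAS5 signal on a log axis for 3 ribosomal RNA control probe sets, 1 point per array, wild type in blue and serf1 in red. In each, the serf1 arrays lie above the wild-type arrays, for example 109 to 173 against 41.2 to 85.6 for the 28S control.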

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

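The tests of chance, exchanged labels and RNA quality were chosen after the results were seen, and the test of harvest time before the clock genes were looked at.

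The 18S and 28S ribosomal RNA controls, outside the main comparison, were brighter on all 3 serf1 arrays than on all 3 wild-type arrays, while the 25S and 5.8S controls overlapped. AFFX-OS-18SrRNA_s_at had a mean of 238.7 in serf1 (SD 148) and 49.3 in wild type (SD 25.3). AFFX-Os_18SrRNA_at had 144.2 (SD 75.4) and 33.5 (SD 24.8), and AFFX-Os_28SrRNA_at 139.5 (SD 32.0) and 61.7 (SD 22.4). In all 3, wild type 3 was the highest wild-type array and serf1 1 the lowest serf1 array, so these signals also moved with the first component. Among 52 control probe sets above background in serf1, 7.69% had genotypes that do not overlap, where chance gives 10%. The 52 were chosen by their serf1 signal alone, which favours controls high in serf1, so the 10% is only a rough reference.

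For the 7 probe sets past the threshold, the 6 arrays allow only 10 splits into 3 and 3, too few for a share under 0.05. The split by genotype called 7, the highest of the others called 5492, and 2 of the 10 called at least 7. A split that calls so many points to a structure of the samples, the division of wild type 1, wild type 2 and serf1 1 from the other arrays. After quantile normalization that split still called 5352. Each of the 8 splits that mix genotype and this division called 0, before and after that normalization.

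That division crosses the genotypes. The brightest of the 64 reporter probe sets, not a rice sequence, argues against exchanged labels of wild type 3 and serf1 1. It measured 3099 on serf1 1 and 12.9 on wild type 3. Its lowest serf1 signal was 166.9 times its highest wild-type signal, an inexact ratio, as all 3 wild-type arrays lay under the background. The argument holds only if the reporter signal comes from the T-DNA of the line, to which the tables used do not tie it. A difference in harvest time was predicted to part the sides in LHY, a morning clock gene. LHY did not part them, as the lowest signal on one side was 0.919 of the highest on the other. PRR1 did, at 26.7 to 45.8 on wild type 1, wild type 2 and serf1 1 against 56.6 to 92.6 on the others. PRR95 was also higher on those others, at 258 to 477 against 135 to 244, and PRR37 lower, at 184 to 218 against 225 to 240. GI, PCL1 and PRR73 overlapped. Harvest time stays open, because overlap in LHY alone cannot exclude a shift that leaves LHY little changed. RNA degradation stays open: 1 of 4 3′ to 5′ ratios, that of actin, parted the arrays along the division, at 4.18 to 4.49 against 4.70 to 5.21, and the other ratios overlapped, which decides nothing. Growth or harvest in separate lots stays open too and was not tested, as the labels give no lot, and no biological explanation was tested.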

How the results depend on the processing

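The component covariate, the background floor and leaving out reporter probe sets were chosen after seeing the data. The count of 7 was 16 with array weights, 13 higher and 3 lower, and 355 with the first principal component of the residuals as a covariate, 114 higher and 241 lower. That covariate is not a usable correction here: in simulated arrays with a shared component it gave a median of 3398 false calls. Every other setting on all 6 arrays gave 5 to 10, and leaving out each array gave 1 to 7. At an unadjusted p under 0.05 there were 7420 probe sets with array weights and 3121 with the replicate block. The cause of the change with array weights was not tested. Whether the same-numbered arrays are pairs stays open. Their deviations from the genotype mean correlated at 0.66, -0.06 and 0.63 for numbers 1, 2 and 3. Across genotypes, the arrays numbered 1 and those numbered 3 correlated best with each other, while serf1 2 and wild type 2 did not. The first component cuts across the genotypes, so these values cannot settle the pairing. The replicate block gave 10 probe sets, all 7 among them, and 7 lists.

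The first probe set of LOC4331398 passed in 19 of 19 settings, and the lower probe set in 12 of 18, losing the call whenever an array was left out, with a log2 difference of -3.84 to -3.37 in those fits against -3.57 with all arrays. Of the 24 calls lost by the 7 probe sets, none changed direction. The 3 lists called became 8 with array weights, 8 with the component covariate and 0 with an estimated correlation, and 0 to 9 when leaving out each array. Of 1387 values for 74 other named genes, 7 passed, all with the component covariate, and 1 changed sign: PRR1, whose log2 difference ran from -0.0746 without serf1 2 to 0.82 without serf1 1. DREB2A and MAPK5 passed in no setting run. No alternative could be run for SERF1, nor robust eBayes for the lists. Bounds depend on the reporter background, under which folds of dim probe sets are not measured.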

Other observations

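The lists differed in how far their means moved between single arrays, which was not tested. They also differ in size, and the mean of a small list moves more easily. Measured genes were 6 for WRKY, 16 for phytoalexins, 7 for photosynthesis, 22 for pathogenesis-related proteins and 5 for glutathione S-transferases. The lists with small spans had 65 for ABA, 15 for phosphate starvation and 21 for aquaporins. Mean log2 signal of the WRKY genes, centred over the 6 arrays, was 0.78, 0.39 and -0.50 on wild type 1 to 3 and 0.60, -0.44 and -0.82 on serf1 1 to 3. The diterpenoid phytoalexin genes, which make antimicrobial compounds of rice, spanned 1.46 between the highest and lowest array, the photosynthesis genes 1.26, the pathogenesis-related proteins 1.12 and the glutathione S-transferases 1.09. Lists at the other end were ABA signalling and synthesis, which spanned 0.10, phosphate starvation at 0.14 and aquaporins at 0.15. None of the members of these lists passed between genotypes.

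The remaining lists held no gene past the threshold either. Camera adjusted p was 0.179 for heat shock proteins and for fermentation, 0.387 for WRKY genes and glutathione S-transferases, and 0.415 for phytoalexin synthesis and for starch and sucrose metabolism. It was 0.585 for the circadian clock, 0.911 for ribosomal proteins, expansins, cytokinin and gibberellin, jasmonate, nitrogen, reactive oxygen and secondary wall lists, and 0.916 for ethylene, iron and phosphate lists. Class III peroxidases, with 4 measured genes, and the study's 2 genes were not tested as lists. Median, mean and test differed in sign for ABA genes, aquaporins and the nitrogen list.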
